A study of Aspergillus nidulans with 8 samples.

How the data were processed

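Gene expression was measured in mycelia of Aspergillus nidulans, a filamentous fungus, with single-colour (Cy3) Agilent arrays of a custom design. Each of the 8 arrays held 1 pool of total RNA from 3 cultures, per the labels. The arrays covered 2 strain labels, the reference strain and a strain deleted for atfA, and 4 conditions, untreated, amphotericin B (AmB), CdCl2 and Congo Red. Every combination of strain label and condition had 1 array, so no combination had a replicate, and the number of arrays limits the precision of every value.

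The deposited scanner files were written by Agilent Feature Extraction 12.0.3.1, per the submitters' processing notes. They hold, per the file headers, a processed signal for each spot, which is a background-subtracted intensity on a linear scale, with the median intensity and the background intensity beside it. The authors also deposited a value table of the whole series, whose values are on a log2 scale; its normalization is not given in the sources used here, its column medians lay between 9.237 and 9.26, and its direction was read from its correlation with the scanner signals. No genome build is named in the files, so no coordinates are given. The 10550 probes, each spotted 4 times, stand for 10550 transcripts. Their identifiers were matched to the locus tags of the RefSeq table of assembly ASM1142v1: 9697 matched and 776 had a gene symbol there. Genes are called by that symbol or otherwise by their AN number; some of the table's symbols are those of orthologues in other species.

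Control spots and spots with an outlier flag (1.46% to 1.9% of spots on an array) were left out, the log2 processed signals of a probe's spots were averaged, and each array was scaled to its own 75th percentile. A gene was tested if its probe was well above background on at least 2 arrays, which left 8633 genes, 7105 of them above background on all 8. The 75th percentile of the processed signal was 335.7 and 261.8 on the AmB arrays and 1062.1 to 1876 on the others. The arrays detected 7689 to 8478 probes each. The median SD between spots of a probe was 0.068 to 0.086 on the log2 scale, which covers the scanner and the slide and not the cultures. Where a probe was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

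The tests were fixed before the data were examined. The AmB, CdCl2, Congo Red and strain comparisons used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 8 arrays, with strain label, treatment and slide as terms, which leaves 2 residual degrees of freedom. The strain labels thus serve as the pair of arrays of a treatment, and the spread is the departure from additivity. The labels do not give the slide, which was read from the barcode in the names of the scanner files. The slide term fits the Congo Red pair exactly, so this spread comes from the untreated, AmB and CdCl2 arrays alone. With the slide term, the Congo Red pair of arrays carries as much weight in a strain value as the other 3 pairs together. Strain dependence of the AmB and CdCl2 responses was tested as an added interaction term without the slide. The design fixed beforehand described this term as a difference of responses between 4 arrays, which was an error found after the fits: it compares the difference between strain labels under the treatment with the mean of that difference over the other 3 conditions. Across genes it correlated with the difference of the responses at r = 0.97 for AmB and 0.64 for CdCl2, and the AmB arrays enter the CdCl2 term. The test was kept as fixed, and for the genes named for AmB the responses of each set are given beside it. Congo Red and untreated arrays lay on different slides within each strain label, in opposite order, so the strain dependence of the Congo Red response cannot be told apart from the slide and is given as values. P-values were adjusted by Benjamini-Hochberg at 0.05. Differences between strain labels are given as labelled reference minus labelled deletion, the opposite sign of the design as first written. The lists of genes were tested with limma's camera at a preset correlation of 0.01, adjusted over all 174 tests of 29 lists in 6 comparisons, and again with an estimated correlation and with fry. Of the preset list members, 83 were kept by symbol, 73 were kept by AN number without a symbol in the table, 10 were dropped because the table gave another gene's symbol, and 3 members were not on the array. The search terms on gene descriptions fixed beforehand could not be used, since neither the files nor the table held descriptions. In their place 201 entries were added by table symbol after the files were seen and before any list value was computed. Counts given as adjusted over the list alone run over the preset and added members together.

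Genes were named by a rule fixed before the data were examined. For each treatment it took, among genes with a symbol, the 8 with the largest mean rise and the 8 with the largest mean fall that passed the test and moved by at least 1 on the log2 scale in the same direction in both strain labels, filled with genes that did not pass where fewer did. For the strain comparison the direction had to hold in all 4 conditions, and for strain dependence the 6 largest each way were taken. Up to 4 members were named per list, and atfA, pyroA and pyrG on every array. The 2 largest changes each way whatever the annotation were added to these.

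The test step was checked on simulated arrays made from the fitted means of the 8633 genes and their SDs after eBayes. In each of 5 simulations 200 genes were changed by known folds. Of genes changed 2-fold, 4-fold and 8-fold, it recovered 2.4%, 50.8% and 94.0% for AmB, 2.0%, 52.4% and 92.0% for CdCl2, 0.4%, 58.8% and 92.8% for Congo Red, and 4.8%, 84.8% and 98.4% for strain. For strain dependence it recovered 2.4%, 54.0% and 92.0% with AmB and 0%, 0% and 10.0% with CdCl2. SDs after eBayes are more alike across genes than those before, and the adjustment depends on the number of changed genes. Recovery in the data can thus be lower. Under Congo Red, for example, AN3246 at 7.58 ± 0.58 did not pass (limma adjusted p = 0.136). Calls of unchanged genes per simulation were 8.0 of 130.0 for AmB, 13.8 of 135.6 for CdCl2, 13.0 of 138.6 for Congo Red, 14.8 of 158.4 for strain, and 14.0 of 137.8 and 1.8 of 26.6 for strain dependence with AmB and CdCl2, each above the nominal 5%. The alternatives tried were normexp background correction with an offset of 50 (on the median signal, as the files used hold no mean signal), quantile and median scaling, other filters on dim probes, the value table, an intensity trend in eBayes, other slide terms, fits on fewer arrays and leaving out single arrays. In the strain and Congo Red fits a Congo Red array could be left out only together with the slide term, and the arrays of the treatment tested were not left out of its strain dependence. An alternative for genes with several probes was void, as each gene had 1 probe.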

Results

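Transcript levels were measured after 0.5 h of stress in 16 h submerged cultures of Aspergillus nidulans carrying or lacking atfA, the gene of a bZIP transcription factor of the stress response. The stresses, with the doses as the labels give them, were 2 mM amphotericin B (AmB), a polyene that binds ergosterol in the fungal membrane, 0.2 mM CdCl2, a heavy metal salt, and 10 mM Congo Red, a dye that binds cell wall glucan and chitin. The labels are the only source for these doses, and their units were not checked against another source. A micro sign lost from at least the AmB dose cannot be excluded, in which case the printed value is too high by 3 orders of magnitude. Each of the 8 arrays, 1 per strain label and condition, held RNA pooled from 3 cultures. There are no replicate arrays, and each p-value measures the departure from additivity between the strain labels, not the spread between cultures. In the fits with a slide term, the Congo Red pair of arrays is fitted exactly and adds nothing to that departure.

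The targeted gene went against the strain labels of the scanner files on all 8 arrays. The atfA probe was not well above background on any of the 4 arrays labelled reference, with processed signals of 2.3 to 3.09, and was bright on all 4 labelled as the atfA deletion, at 3270 to 9710. In the value table the reference columns held atfA at 13.66 to 14.6 and the deletion columns at 6.19 to 6.26 on the log2 scale, as their labels say. Each of the 8 columns of that table correlated best with an array of the other strain label, with Pearson's r across genes of 0.971 to 0.990 against 0.910 to 0.952 with its own array. For 2 of the 8 columns, reference untreated and reference CdCl2, the best match also had another treatment label. The scanner files are used here under their own labels, as "the arrays labelled reference" and "the arrays labelled deletion", and every direction between strains below is one between those labels, against which atfA speaks. Of the other marker genes, pyroA lay at 3.12 to 4.88 on the arrays labelled reference and at 1.68 to 2.06 on those labelled deletion, on the log2 scale relative to the array's 75th percentile. For pyrG the ranges were 1.32 to 3.07 and 2.11 to 2.73.

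**Figure D1:**
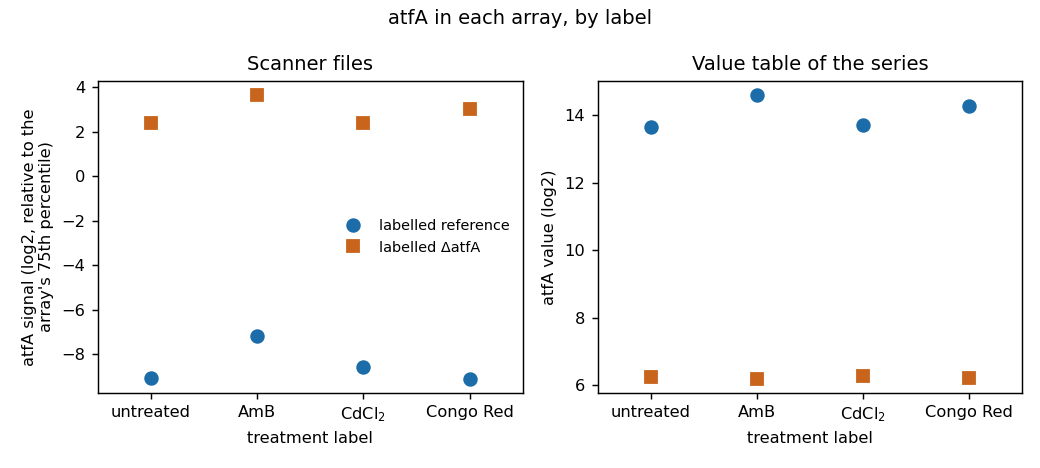
atfA on each array against the treatment label: left, scanner signal on the log2 scale relative to the array's 75th percentile; right, the value in the value table (log2); circles are labelled reference and squares labelled deletion, 1 array each. The scanner signals labelled deletion lie at 2.37 to 3.64 and those labelled reference at -9.09 to -7.19, while in the value table the order is the opposite.

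The first comparison asked which genes respond to AmB in both strain labels. AmB had the widest response of the 3 treatments. Among the largest risers were 2 genes of phenylalanine and tyrosine breakdown: hmgX (AN1898) rose by 7.52 ± 0.85 on the log2 scale (mean ± SE of the limma fit) and maiA (AN1895), the gene of maleylacetoacetate isomerase, by 4.70 ± 0.86. The transporter gene mfsA (AN9168) rose by 5.68 ± 0.42, which was 5.03 on the arrays labelled reference and 6.33 on those labelled deletion. The nitrate transporter gene crnA (AN1008) and the nitrate reductase gene niaD (AN1006) fell, by 2.50 ± 0.33 and 2.33 ± 0.36, while the list of nitrogen assimilation did not pass camera. The alpha-1,3-glucan synthase gene ags2 (AN5885) fell by 3.75 ± 0.68.

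Of 8633 genes tested, 1014 passed at an adjusted p of 0.05 in limma, 742 higher and 272 lower. In single arrays, 1017 genes were at least 2-fold higher and 594 at least 2-fold lower under both strain labels, where independent lists of these sizes would share 337.9 and 225.9, and the responses correlated across genes at r = 0.69 (genes are not independent replicates). Among genes with a symbol, 40 risers and 30 fallers met the naming rule. Besides those above, the largest risers were farB1 (AN1425) at 4.07 ± 0.39, dspC (AN4419) at 3.21 ± 0.54, hxB (AN1637), which activates molybdenum enzymes, at 3.20 ± 0.30, and scw4 (AN3727) at 3.17 ± 0.61. MAT2 (AN4734), a mating-type gene, was at least 8.37-fold higher. The other fallers were sclB (AN0585), a regulator of development, which was at least 5.18-fold lower (0.96 higher with normexp), pfa4 (AN1565) at -2.51 ± 0.35, the siderophore transporter family gene mirD (AN6238) at -2.46 ± 0.35 (0.18 with normexp), gmtA (AN8848), a GDP-mannose transporter gene, at -2.44 ± 0.34, and sld2 (AN3040) at -2.26 ± 0.38. The limma adjusted p of these 16 genes lay between 0.0116 and 0.0413. The largest changes without regard to annotation were AN3125 at 9.86 ± 0.44, AN4394 at -5.01 ± 0.59, AN9115, at least 253-fold higher, and AN9444, at least 14.9-fold lower.

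The genes of sterol biosynthesis, the pathway that makes ergosterol, lay lower as a list (20 genes, median -0.95, camera adjusted p = 0.00987; p = 0.254 with an estimated correlation). Of these, 2 fell and none rose over all genes tested, and 8 fell when adjusted over the list alone. The 2 were erg2 (AN0451), sterol C-8 isomerase, at -1.95 ± 0.30 and erg5 (AN4042), sterol C-22 desaturase, at -1.85 ± 0.34, while erg13 (AN4923), the gene of HMG-CoA synthase, was at -2.41 ± 0.71 and erg4 (AN10648) at -2.05 ± 0.53 without passing. The sterigmatocystin cluster, which makes a polyketide mycotoxin, lay higher (11 genes, median 1.77, camera adjusted p = 0.0135; p = 0.323 with an estimated correlation), with 4 genes that rose and none that fell, and 6 that rose when adjusted over the list alone. Its examples were AN7817 at 2.52 ± 0.34, AN7811 at 2.42 ± 0.49 and AN7825 at 1.85 ± 0.29. Some members were dim. The probes of AN7819 and AN7821 were not well above background on any array labelled reference. Those of AN7804 and AN7823 were not on the untreated array of that label. Part of this list's shift may thus come from signals near background. The lists of ribosome biogenesis (27 genes, median -0.84, camera adjusted p = 0.0180; p = 0.560 with an estimated correlation) and mitochondrial import (8 genes, median -1.0, camera adjusted p = 0.0487; p = 0.400 with an estimated correlation) lay lower, with no member past the test. The shift was larger on the arrays labelled reference, with medians of -1.77 and -1.48. On those labelled deletion the medians were 0.08 and -0.42, so ribosome biogenesis did not lie lower there. Their largest members were loc1 (AN6556) at -1.96 ± 0.45 and tom40 (AN6510), the pore of the outer membrane translocase, at -1.77 ± 0.41. Other lists were not past the camera test. Among their members, the peroxisome genes pex19 (AN4899) at 2.24 ± 0.29 and pex10 (AN5681) at 1.63 ± 0.29 rose, as did AN7388, listed as the catalase-peroxidase cpeA, at 3.35 ± 0.43, AN6653, listed as the malate synthase acuE, at 2.59 ± 0.29, and prnD (AN1731), proline oxidase, at 2.39 ± 0.47.

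The count depends on the scaling and on single arrays. It split into 530 higher and 480 lower under quantile normalization and 469 and 462 in the value table, and came to 138 without the untreated array labelled reference and 4417 without the AmB array labelled deletion. Both AmB arrays were dimmer than the other 6. The lowest scaled signal of a probe well above background was -5.67 and -5.58 on them and -7.95 to -7.32 on the others. A dim probe can thus appear to rise under AmB. The atfA probe, for example, passed at 1.56 ± 0.32 (limma adjusted p = 0.0448). Its 1.87 on the arrays labelled reference came from signals not above background. Among genes above background on all 8 arrays, 599 passed as higher and 353 as lower.

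**Figure D2:**
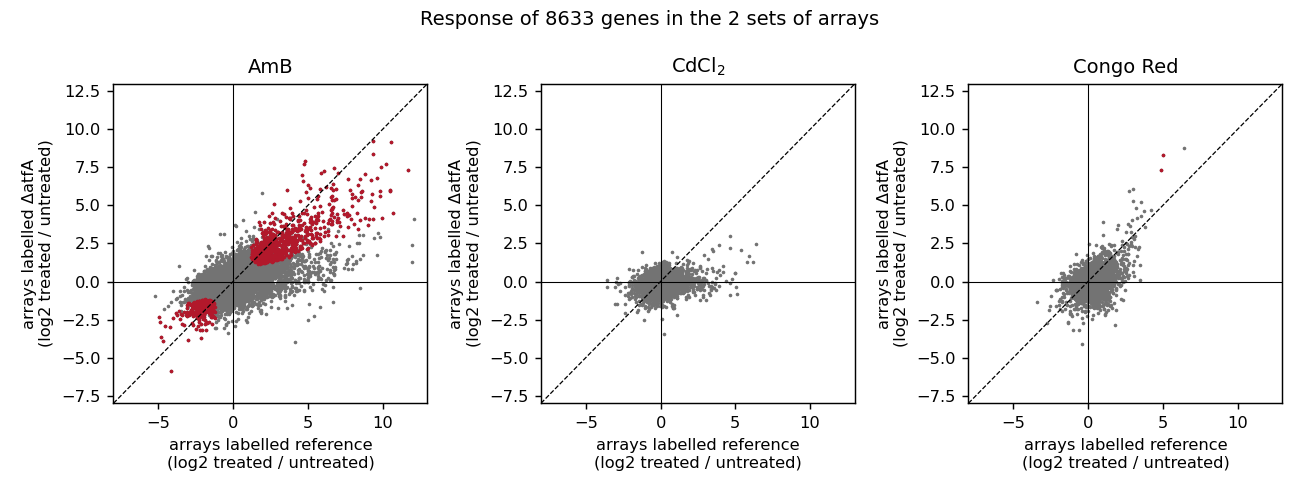
Log2 ratio of treated to untreated in the arrays labelled reference (x axis) and labelled deletion (y axis) for 8633 genes under each treatment; each point is a gene, red points passed limma's test at an adjusted p of 0.05, and the dashed line marks equal responses. The SD of the response on the x and y axes was 1.91 and 1.21 under AmB, 0.63 and 0.39 under CdCl2, and 0.60 and 0.56 under Congo Red.

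The second comparison asked the same of CdCl2, a metal that binds thiols. No gene passed in limma (0 of 8633 at an adjusted p of 0.05; 114 at an unadjusted p under 0.05, where 432 would be expected by chance). The largest responses lay in genes without a symbol, AN2576 at 4.44 ± 1.03 and AN3563, at least 5.21-fold higher, with AN6869 at -2.26 ± 0.46 and AN2350 at -2.21 ± 0.80. The list of chaperones lay higher (14 genes, median 0.73, all 14 above 0, camera adjusted p = 5.04e-08; p = 0.153 with an estimated correlation), and that of iron and siderophores lower (14 genes, median -0.32, camera adjusted p = 7.6e-05; p = 0.0378 with an estimated correlation). Both calls were lost with the estimated correlation, after adjustment over all lists.

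Among chaperones, bipA (AN2062), the Hsp70 of the endoplasmic reticulum, had a mean response of 1.11 ± 0.32, with 0.91 on the arrays labelled deletion. hsp90 (AN8269) stood at 1.94 on the arrays labelled reference and 0.15 on those labelled deletion, and fes1 (AN6543), an exchange factor of Hsp70, at 2.42 and -0.50. The siderophore genes AN8539, listed as sidG, sidI (AN0609), mirB (AN8540), a siderophore transporter gene, and sidH (AN6235) had mean responses of -1.56 ± 0.45, -1.15 ± 0.35, -0.92 ± 0.29 and -0.86 ± 0.29. Ribosome biogenesis lay slightly higher (27 genes, median 0.32, camera adjusted p = 0.000948; p = 0.463 with an estimated correlation), as did drug transporters (5 genes, median 0.24, camera adjusted p = 0.0462; p = 0.107 with an estimated correlation). No member of these 4 lists passed limma's test, over all genes or adjusted over the list alone. The 3 genes the naming rule gave, none past the test, were car2 (AN1810) at -1.32 ± 0.98, sidI and esdC (AN9121), a gene of early sexual development, at -1.12 ± 0.67. No gene met the rule on the higher side.

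At least 2-fold changes under CdCl2 numbered 371 higher and 238 lower on the arrays labelled reference, and 45 and 133 on those labelled deletion. Of these, 22 and 26 were shared, where 1.9 and 3.7 would be expected of independent lists. The AmB arrays add to the spread of this fit. Without them the count was still 0, with 663 at an unadjusted p under 0.05 against 432 expected by chance. That fit has fewer residual degrees of freedom, so its count of 0 cannot show whether the AmB spread hid CdCl2 genes. With the value table, whose treatment labels differ from those of the scanner files, the medians of the iron list and the ribosome biogenesis list turned to 0.03 and -0.31.

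The third comparison asked which genes respond to Congo Red. Genes of iron uptake lay lower in the mean of both sets. The list of iron and siderophores had all 14 fitted values below 0 and a median of -0.94 (camera adjusted p = 1.9e-11, and p = 0.0156 with an estimated correlation). Of its genes, 7 fell when adjusted over the list alone, none over all genes. After adjustment over all lists the call was lost with the estimated correlation. Its largest members were AN8539, listed as sidG, at -1.67 ± 0.45, mirB at -1.65 ± 0.29, sidD (AN6236), the peptide synthetase of fusarinine C, at -1.58 ± 0.35, and AN5823, listed as the ornithine monooxygenase sidA, at -1.53 ± 0.29. The list's median was -0.27 on the arrays labelled reference and -1.46 on those labelled deletion, each between different slides and without a test. Cell wall genes did not move as a list in these data, with gel1 (AN7657), a glucanosyltransferase gene, at -0.46 ± 0.42 and the chitin synthase gene chsB (AN7032) at 0.40 ± 0.49.

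In limma 2 genes passed, AN8435, at least 57.0-fold higher (adjusted p = 0.0336), and AN11455, at least 38.1-fold higher, both higher on each set of arrays, and 259 had an unadjusted p under 0.05 against 432 expected by chance. The largest fitted response, AN3246 at 7.58 ± 0.58, had a limma adjusted p of 0.136. The largest on the lower side were AN5429 at -2.73 ± 0.40 and AN9343 at -2.38 ± 0.60. In single arrays 124 genes were at least 2-fold higher and 28 at least 2-fold lower under both labels, where 14.8 and 3.3 would be expected of independent lists. Named genes that met the rule without passing were hmgX at 1.97 ± 0.85, the zinc transporter gene zrfA (AN8337) at 1.77 ± 0.61, prnD at 1.55 ± 0.47, ugd2 (AN9172) at 1.34 ± 0.59, and, on the lower side, mirB, sidD and ergS (AN8148) at -1.51 ± 0.61. The penicillin cluster lay lower (3 genes, median -1.30, camera adjusted p = 0.0073; p = 0.178 with an estimated correlation), as did amino acid biosynthesis (15 genes, median -0.34, camera adjusted p = 0.0103; p = 0.123 with an estimated correlation) and glycolysis (11 genes, median -0.29, camera adjusted p = 0.0135; p = 0.245 with an estimated correlation). When adjusted over the list alone, 1 penicillin gene fell and no gene of the other pair of lists did; lysB (AN5206) was at -0.80 ± 0.29 and pgkA (AN1246), phosphoglycerate kinase, at -0.47 ± 0.31.

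The count of 2 rose to 83 without the AmB arrays, and fell to 0 with no slide term, with quantile normalization and with the value table. Within each strain label, Congo Red and untreated lay on different slides, so the slide cancels only in the mean of both labels. The Congo Red arrays also add nothing to the spread of this fit. Its p-values thus hold no measure of how far the Congo Red responses of the sets differ.

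**Figure D3:**
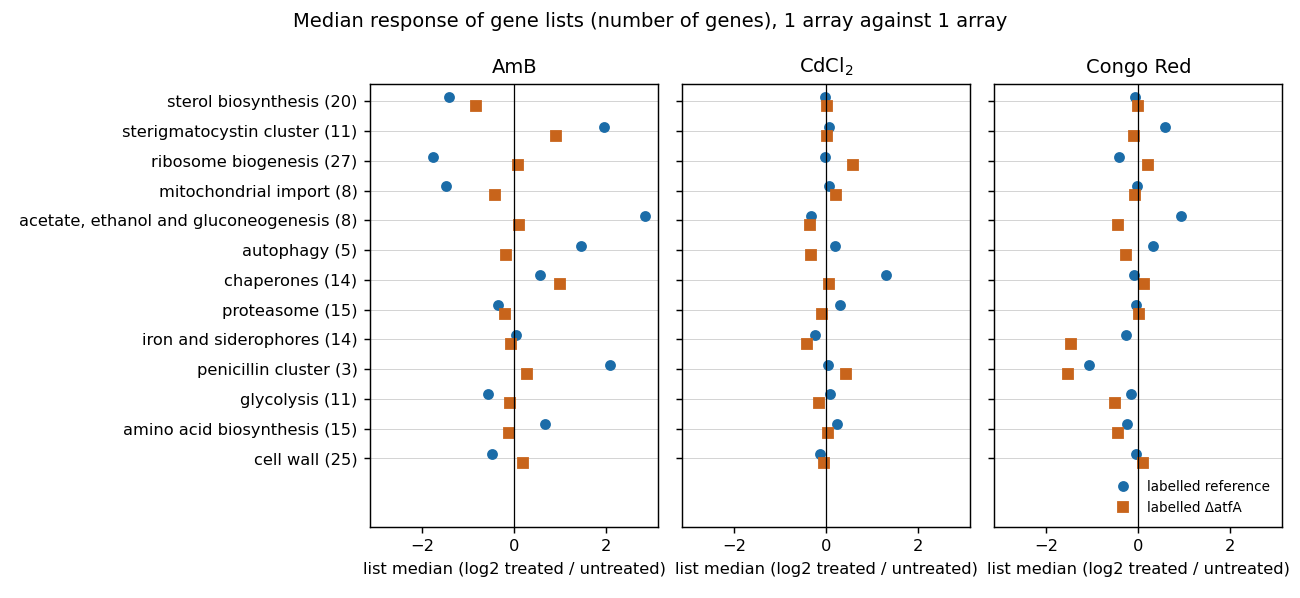
Median log2 ratio of treated to untreated over the genes of 13 lists (y axis, number of genes in brackets) under each treatment; circles are arrays labelled reference and squares arrays labelled deletion, each 1 array against 1 array. Sterol biosynthesis lies at -1.41 and -0.84 under AmB, chaperones at 1.29 and 0.06 under CdCl2, and iron and siderophores at -0.27 and -1.46 under Congo Red.

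The fourth comparison set the strain labels against each other over the 4 conditions. Each strain value weighs the Congo Red pair of arrays as much as the other 3 pairs together, while the spread comes from those 3 pairs alone. Apart from atfA, 2 clusters of secondary metabolism lay lower as lists, and single genes of conidiation differed while the list of asexual development did not pass camera. The penicillin cluster lay lower on the arrays labelled reference, those with no atfA signal above background (3 genes, median -3.98, camera adjusted p = 0.000239; p = 0.123 with an estimated correlation). So did the sterigmatocystin cluster (11 genes, median -0.77, camera adjusted p = 7.6e-05; p = 0.199 with an estimated correlation). The hydrophobin gene rodA (AN8803) was higher on those arrays by 3.32 ± 0.45, ivoA (AN10576), of the conidiophore pigment, by 2.02 ± 0.27, and ags2 by 4.02 ± 0.56.

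In limma 161 genes passed, 74 higher and 87 lower on the arrays labelled reference. In single pairs of arrays, 144 genes were at least 2-fold higher and 206 at least 2-fold lower in all 4 conditions, here with no further filter on background. The atfA probe was at least 935-fold lower (adjusted p = 0.00123). The penicillin gene AN2621, listed as acvA, was at least 15.7-fold lower and passed, while AN2622, listed as the isopenicillin N synthase gene ipnA, stood at -3.98 ± 0.61 (limma adjusted p = 0.0616) and AN2623, listed as aatA, at -2.22 ± 0.47. All 3 were lower when adjusted over the list alone. In the sterigmatocystin cluster AN7821 passed, at least 2.33-fold lower, and 5 genes were lower when adjusted over the list alone, with AN7822 at -2.34 ± 0.41. The other annotated genes past the test were agdC (AN0941) at 2.09 ± 0.23 and fmaG (AN3394) at -2.71 ± 0.31. Named without passing were ivoB (AN0231) at 4.33 ± 0.74, aah1 (AN6078) at 2.12 ± 1.02, hmgX at 1.93 ± 0.69 and the proline transporter gene prnB (AN1732) at 1.90 ± 0.44. On the lower side these were coaT (AN1547) at -4.42 ± 0.89, the dipeptidyl peptidase genes dppIV (AN6438) at -2.54 ± 0.67 and dppV (AN2572) at -1.96 ± 0.30, gatA (AN2248) at -1.93 ± 0.36, ish1 (AN4940) at -1.80 ± 0.58 and nopA (AN3361), an opsin gene, at -1.78 ± 0.32. The catalase gene cat1 (AN9339) was lower in each of the 4 conditions, by -2.83 to -1.10, with a fitted value of -1.72 ± 0.29 that did not pass (limma adjusted p = 0.0755).

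In the values of the series table, 107 genes passed, 37 higher and 70 lower on the columns with low atfA. The count was 1173 without the AmB arrays, 526 with no slide term and 84 among genes above background on all 8 arrays.

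The fifth comparison asked whether the response to AmB differed between the strain labels. The test compares the difference between strain labels under AmB with its mean over the other 3 conditions. Genes of ribosome biogenesis lay lower under AmB on the arrays labelled reference, with a median of -1.77, and near 0 on those labelled deletion, with a median of 0.08. The median of the interaction was -1.43 (27 genes, camera adjusted p = 3.39e-08; p = 0.294 with an estimated correlation). Genes of acetate and ethanol use and gluconeogenesis showed the opposite, with medians of 2.85 and 0.10 and a median interaction of 1.74 (8 genes, camera adjusted p = 0.0268; p = 0.323 with an estimated correlation). The chitin synthase gene chsD (AN1046) rose by 4.75 on the arrays labelled reference and was not above background under AmB on those labelled deletion. On the arrays labelled reference hmgA (AN1897), homogentisate dioxygenase, also rose more, by 6.42 against 1.57, as did fahA (AN1896), fumarylacetoacetase, by 6.29 against 1.73.

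In limma's interaction test 427 genes passed, 361 with a higher and 66 with a lower response on the arrays labelled reference. The interaction was 4.43 ± 0.38 for chsD, 4.36 ± 0.69 for pex7 (AN0880), a peroxisomal import receptor, 4.23 ± 0.53 for fahA, 4.16 ± 0.66 for hmgA, 3.70 ± 0.50 for coaT, and 3.57 ± 0.33 for pmcB (AN4920), a calcium pump gene. On the lower side it was -2.84 ± 0.46 for aclA (AN2435), of ATP citrate lyase, -2.31 ± 0.39 for erg13, -2.24 ± 0.33 for ilv3 (AN6346), of branched-chain amino acid synthesis, -2.19 ± 0.36 for abaA (AN0422), a regulator of conidiation, -1.86 ± 0.33 for mrsA (AN3690) and -1.85 ± 0.33 for the chitin synthase gene chsE (AN6318). On the arrays labelled reference and deletion, coaT responded by 5.09 and 1.01, pmcB by 3.11 and -0.55, aclA by -3.56 and -0.63, erg13 by -3.75 and -1.06, ilv3 by -1.25 and 0.87, mrsA by -1.79 and -0.11 and chsE by -1.58 and 0.10. The gene pex7 was higher by 3.63 on the arrays labelled reference and at least 1.60-fold lower on those labelled deletion, and abaA was higher by 3.57 on the arrays labelled deletion and not above background under AmB on those labelled reference. The interactions of chsD, pex7 and abaA thus rest in part on signals near background. The limma adjusted p of these 12 genes lay between 0.0189 and 0.0463. No ribosome biogenesis gene passed over all genes, and 19 were lower when adjusted over the list alone, among them spb4 (AN3176) at -2.28 ± 0.43 and lcp5 (AN5340) at -2.16 ± 0.41. In the acetate list AN5634, listed as the isocitrate lyase acuD, passed at 6.50 ± 0.74, and 6 genes were higher when adjusted over the list alone. Mitochondrial import lay lower (8 genes, median -1.01, camera adjusted p = 0.0136; p = 0.195 with an estimated correlation; 3 genes lower when adjusted over the list alone), as did ribosomal proteins and translation initiation (12 genes, median -0.62, camera adjusted p = 0.0384; p = 0.341 with an estimated correlation). Autophagy lay higher (5 genes, median 1.21, camera adjusted p = 0.0487; p = 0.326 with an estimated correlation; 4 genes higher when adjusted over the list alone), with atg15 (AN5919), a lipase of the vacuole, at 2.50 ± 0.36 and past the test.

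Each side of the interaction under AmB rests on 1 array. The count was 0 without the untreated array of either label, 182 with the untreated and CdCl2 arrays labelled deletion exchanged, and 1413 (746 higher and 667 lower) under quantile normalization, and with normexp the interaction turned to 0.44 for abaA, 0.46 for mrsA and 0.45 for chsE.

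The sixth comparison asked the same of CdCl2. The chaperone list responded on the arrays labelled reference, with a median of 1.29, and hardly on those labelled deletion, with 0.06, where bipA stood at 0.91. Its median interaction was 1.46 (14 genes, camera adjusted p = 4.12e-10; p = 0.0301 with an estimated correlation, a call lost after adjustment over all lists), with sti1 (AN9124), a co-chaperone of Hsp90, at 1.60 and -0.71 on the pair of sets, and fes1 and hsp90 as above. The proteasome list, with medians of 0.30 and -0.10, had an interaction of 0.45 (15 genes, all above 0, camera adjusted p = 0.000597; p = 0.137 with an estimated correlation), with rpt3 (AN2904) at 0.77 and 0.09. The secretory pathway, with medians of 0.31 and -0.09, had 0.53 (18 genes, camera adjusted p = 0.0018; p = 0.204 with an estimated correlation), with sec23 (AN0261), of vesicle coats, at 0.65 and -0.03. Nitrogen assimilation, with medians of 0.08 and -0.36, had 0.50 (12 genes, camera adjusted p = 0.0358; p = 0.134 with an estimated correlation), with a median of -0.04 in the value table. The acetate list had -1.01 (8 genes, camera adjusted p = 0.0374; p = 0.299 with an estimated correlation), but its responses to CdCl2 were -0.34 and -0.35, so this value comes from the other conditions, AmB among them.

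No single gene passed limma's interaction test for CdCl2 (0 of 8633, with 154 at an unadjusted p under 0.05). None passed without the AmB arrays either (518 at an unadjusted p under 0.05), in a fit with fewer residual degrees of freedom. The largest named values, none past the test, were 2.35 ± 0.64 for ergS, 2.32 ± 1.09 for the calnexin gene clxA (AN3592), 2.25 ± 0.47 for sti1, 2.16 ± 0.60 for hsp90, 2.15 ± 0.67 for fes1 and 2.02 ± 0.53 for nudC (AN5181). On the lower side they were mcsA (AN6650), methylcitrate synthase, at -2.77 ± 1.23, psf3 (AN5574) at -2.11 ± 0.57, aspf2 (AN1832) at -2.11 ± 0.68, acuM (AN6293) at -2.04 ± 0.85, fahA at -1.90 ± 1.85 and chsD at -1.76 ± 1.93. The probe of acuM was not above background on the untreated and CdCl2 arrays, that of psf3 on those labelled deletion and under CdCl2 on those labelled reference, and those of mcsA and chsD under CdCl2 on those labelled reference, so these 4 values are rough. The values of fahA and chsD do not come from CdCl2 but mostly from the AmB arrays: under CdCl2 fahA responded by 0.37 and 0.41 on the arrays labelled reference and deletion, and chsD by -0.04 on those labelled deletion. For clxA the responses to CdCl2 were 1.28 and 0.32, a smaller difference than its interaction. The same held for mcsA, at -2.19 and -0.97, and for acuM, at -1.30 and -0.31, both with dim probes. For Congo Red the difference between strain labels is confounded with the slide. As values without a test, 579 genes were at least 2-fold higher and 120 lower on the arrays labelled reference, and 221 and 234 on those labelled deletion.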

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

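The tests in this part were chosen before their results were seen. The response to AmB differed between the arrays labelled reference and those labelled deletion for 427 genes by limma's interaction test, and for each of the 12 genes named for it. On the log2 scale the interaction, the difference between strain labels under AmB less its mean in the other 3 conditions, was 4.43 for chsD, 4.36 for pex7, 4.23 for fahA, 4.16 for hmgA, 3.70 for coaT, 3.57 for pmcB, -2.84 for aclA, -2.31 for erg13, -2.24 for ilv3, -2.19 for abaA, -1.86 for mrsA and -1.85 for chsE. For chsD and pex7 the AmB array labelled deletion, and for abaA that labelled reference, was not well above background, so these 3 values are rough. Each group had 1 array, so no group could be searched for a sample standing apart.

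The AmB response was wider as a whole on the arrays labelled reference, with an SD over genes of 1.91 against 1.21, a ratio of 1.57. Low signal of dim genes does not account for it, as the ratio was 1.61 in the 2159 genes with the highest mean level. This cannot exclude a difference between the AmB arrays that acts on bright genes too. The dimmer of the AmB arrays was the one labelled deletion, where the response was narrower. An unusual untreated array does not account for all of the width either. The ratio was 1.44 with the CdCl2 array and 1.43 with the Congo Red array of each set as the baseline. The ratio of the median absolute deviations was 1.64 with the untreated array and 1.51 and 1.39 with these baselines. Part of the width may thus come from the untreated arrays. The count of 427 genes, however, did not hold without the untreated array of either label. Whether the scaling sets the count of genes is open: it was 1413 under quantile normalization against 427, a rise that neither bound set in advance had foreseen. A difference between the strains in their response to AmB, a difference in exposure between 2 pools of cultures, and a difference in signal between the AmB arrays remain as explanations. They may hold alone or together, as each value rests on single arrays.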

How the results depend on the processing

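Fits without the AmB arrays and with the untreated and CdCl2 arrays labelled deletion exchanged were chosen after seeing the data. Leaving out 1 array of a treatment can let that treatment's term fit the other array exactly. The fit is then the same as without both, as with either AmB array in the strain comparison, so such counts are not separate checks. The CdCl2 and CdCl2 strain-dependent counts stayed at 0 under every alternative run. AmB genes numbered 1014; 3991 with normexp (3520 higher, 471 lower), 3323 with no filter, 1994 with no slide term and 560 on the 4 arrays of AmB and untreated; leaving out 1 array gave 138 to 4417 (138 and 465 without the untreated array labelled reference and deletion, 2152 and 4417 without the AmB arrays, 560 without either CdCl2 array). Congo Red genes numbered 2; 5 with normexp, 83 without the AmB arrays, and 0 with quantile normalization, genes above background on all 8 arrays, the value table, an intensity trend, no slide term, the 4 arrays alone or the exchange; leaving out 1 array gave 0 to 83, the lowest without either untreated array and the highest without either AmB array, and a Congo Red array could be left out only with the slide term (2 and 0 without that labelled reference and deletion). Strain genes numbered 161; 84 among genes above background on all 8 arrays, 107 with the value table, 526 with no slide term and 1173 without the AmB arrays; leaving out 1 array gave 129 to 1173, the highest without either AmB array, and 222 without either Congo Red array and the slide term. AmB strain-dependent genes numbered 427; 1206 with normexp, 1413 with quantile normalization, 1013 with the value table (623 higher, 390 lower), 848 with an intensity trend, 1011 with slide as a block and 182 with the exchange; leaving out 1 array gave 0 to 1011 (0 without either untreated array, 210 without either CdCl2 array, 1011 without either Congo Red array). Genes at least 2-fold changed in both sets numbered 1611, 48 and 152 under AmB, CdCl2 and Congo Red; 2839, 237 and 399 at 1.5-fold, and 756, 11 and 56 at 3-fold, as a lower or higher threshold must. Of 24 list calls, 0 held with an estimated correlation and 0 with fry, while 21 held with normexp, 19 with quantile normalization, 24 with median scaling and 16 with the value table. The median AmB response of all genes was -0.01. It was 0.69 with normexp, -0.27 with quantile normalization and -0.20 in the value table. The normexp run changed the input signal and added an offset of 50 together, and neither was varied alone. Signs turned with normexp for sclB (0.96) and mirD (0.18) under AmB, for abaA (0.44), mrsA (0.46) and chsE (0.45) in the AmB strain dependence and for acuM (0.01) in that of CdCl2; with the value table for car2 (0.08), sidI (0.00) and esdC (0.01) under CdCl2; with the exchange for car2 (0.26) and sidI (0.08). By its own labels the value table put atfA 7.84 higher in the reference, while in the scanner files it was at least 935-fold lower on the arrays labelled reference. Other causes were not tested. An alternative for genes with several probes was not run, as each had 1 probe. Low signal on the AmB arrays limits values of dim genes there.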

Other observations

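The 3 tests on labels, the test of exchanged arrays for the chaperone pattern, the choice of splits with 1 array per treatment and the count of neighbours among AmB risers were chosen after the result was seen. Genes that differed at least 2-fold between the strain labels in all 4 conditions, with no further filter on background, often lay side by side. Of the 326 such genes placed in the gene order of the RefSeq table, 64 pairs were neighbours among the tested genes, against a mean of 13.16 and at most 30 in 10000 shuffled orders (permutation p = 1e-04, the smallest this number of orders can give), and there were 7 runs of at least 3 genes. These were chosen after their values were seen. AN7909, AN7911 and AN7912, of the orsellinic acid cluster, were higher on the arrays labelled reference by means of 3.32, 3.28 and 3.37 on the log2 scale. The penicillin genes AN2622 and AN2623 were lower by -3.93 and -2.38, and AN2621 at least 15.7-fold. In a run of 4, AN7892, AN7895 and AN7896 were lower by -3.21, -2.35 and -3.34 while AN7893 between them was higher by 2.93.

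The 100 genes with the largest AmB rise in both sets held 7 neighbouring pairs against a mean of 0.99 in shuffled orders (permutation p = 1e-04), and the 100 with the largest fall held 5 against 1.08 (permutation p = 0.005). The fallers had a run of 3, AN5888, luA (AN5886) and ags2. Across sets that share no array, genes at least 2-fold higher, here with no filter on background, under AmB on the arrays labelled deletion (1498) and under Congo Red on those labelled reference (617) shared 297, where 107.1 would be expected of independent lists. With the sets the other way round there were 149 against 63.9. Shared fallers were 29 against 14.5 and 69 against 56.1. For AmB and CdCl2 the shared risers were 182 against 68.2 and 25 against 12.6, but the shared fallers were 47 against 29.4 and 17 against 33.5, and the correlation across genes was 0.17 and -0.19, so the 2 pairs of sets went different ways. No test of these overlaps was run.

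Treatments pair the arrays, so the split by strain label was compared with the splits that hold 1 array per treatment, although all splits had been planned. Of these, 7 could be fitted, the labels' own included, too few for a share under 0.05; 1 of the 7, the labels' own, gave as many as 161 genes, and the highest other gave 0. At an unadjusted p under 0.05 the labels gave 1121 genes and the highest other of these splits 1267. Over all 31 splits into 4 and 4 that could be fitted, 4 gave as many unadjusted genes, the labels' own included.

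The first pattern is the atfA signal that goes against the strain labels of the scanner files. A probe outside the deleted part, or one that takes up another transcript, would leave signal on all arrays, but the sets differed by at least 9.87 on the log2 scale. An exchange of the strain labels of the scanner files is the explanation that the tables bear out: 8 of 8 columns of the value table, where atfA follows the labels, matched an array of the other strain label best. Whether the untreated and CdCl2 arrays labelled deletion are also exchanged, as the value table has them, is not settled. Against it, 28 genes moved the same way in both CdCl2 responses among the 100 largest risers and fallers and 3 opposite ways. Across the 7105 genes above background on all arrays, however, these responses correlated at only r = 0.17. The CdCl2 response labelled deletion correlated at -0.19 with AmB and -0.16 with Congo Red labelled reference, signs that an exchange would turn. Shared risers in those pairs, 25 against 12.6 and 11 against 3.3 expected, do not go with an exchange. For the strain, then, the values of both sources go with the labels of the table. What stays open is whether the treatment labels of its 2 columns or those of the scanner arrays are right.

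The other pattern is the chaperone list, with a median of 1.29 under CdCl2 on the arrays labelled reference and 0.06 on those labelled deletion. An exchange of the untreated and CdCl2 arrays labelled deletion would only turn the sign of the median of 0.06. With chaperones left out, 28 of the largest risers and fallers moved the same way in both sets and 3 opposite ways, as before. Only 2 chaperones were among the 100 largest risers of the arrays labelled reference, so this repeats the test above and adds no evidence. A CdCl2 pool labelled deletion that took up little CdCl2 may account for the chaperone pattern. The 100 largest risers of the arrays labelled reference, chaperones left out, had a median of -0.07 in that pool against 2.16 in their own set. The value of -0.07 is lowered by picking genes on the other set. Against a pool with no CdCl2 response stand 22 and 26 genes at least 2-fold higher and lower in both sets, where 1.9 and 3.7 would be expected of independent lists. A difference between the strains stays open beside it.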
